A study of Mus musculus with 27 samples.

How the data were processed

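Expression was measured with 27 Affymetrix mouse expression arrays of lung, liver and kidney from control and MV+SA mice, with 1 column of values per array and the group of each array taken from its label. The values were deposited on a log2 scale after RMA, per the submitters' processing notes; the version of RMA is not given in the sources used here. RMA corrects background, normalizes by quantiles and combines probes into probe sets by median polish. Value distributions matched within an organ and differed between organs, so levels were compared only within an organ. RMA's quantile step sets the arrays normalized together to 1 distribution, so a shift of most genes in 1 direction cannot be seen in such values.

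Of 45101 probe sets, 34958 were paired with 1 gene, 932 with several genes and 9211 were unnamed here; 64 control probe sets were left out of the gene tests. Old symbols were updated through the Entrez identifier, of which 18033 were found in the reference gene table. Probe sets paired with several genes were not used. Each gene was represented by its probe set with the highest mean over all arrays (9011 genes had several), which gave 18195 genes. A gene was tested where that probe set exceeded the array's 40th percentile on at least 3 arrays, which left 15453 genes and removed 2742. Of the named genes, 28 rested on a probe set that the array design marks as able to cross-hybridise. No coordinates are given, since no genome build was used.

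Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 model of 6 group means over all 27 arrays. Contrasts were MV+SA minus control in each organ and the difference of that contrast between each pair of organs. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each contrast, with 0.05 as the threshold, and changes are log2 differences with their standard errors (SE). Overlaps between organs were set beside n1 × n2 / N, the number shared by independent lists, and Pearson's r and Spearman's rho of the changes were taken across genes, for 3 pairs of organs.

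The gene lists numbered 35, of which 22 were pathways or processes and 13 were markers of cell types, with 639 different genes, of which 62 were not analysed here. In each organ 34 lists with at least 5 genes tested were compared with all other genes by limma's camera at its preset correlation of 0.01, with adjustment over the lists of that organ. Every camera test was repeated with the correlation estimated from the data, with which 3 lung lists, 0 liver lists and 0 kidney lists passed (10, 2 and 5 at an unadjusted p under 0.05). With limma's fry, which asks whether a list's genes move 1 way without comparing them with other genes, 23, 2 and 17 passed. Members of a list were counted over all genes tested and adjusted over the list alone.

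Named genes followed a fixed rule. In each organ these were the 15 higher and 10 lower genes with the largest changes among those past the threshold whose MV+SA arrays all lay beyond all controls. For each list and organ they were up to 4 members past the threshold with the largest change, and over organs the 15 higher and 10 lower genes called the same way in all 3 with the largest smallest change. For each difference between organs they were the 5 largest in each direction. A few other genes are also named: those that moved against most of their list, and single members of a list set beside its count. These were chosen after their values were seen.

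The design, the lists, the naming rule and most alternatives were fixed before the data were examined. Those alternatives were each organ's own arrays, no filter, a 60th percentile filter, the mean of all probe sets of a gene, eBayes with trend and robust settings, array weights, quantile normalization over all arrays, arrays centred on their median, the replicate number as a block, a size limit of 1 on the log2 scale, and leaving out each array in turn. Chosen after seeing the data were a term for the 3′-to-5′ class, leaving out the 4 arrays of the other class, and leaving out liver MV+SA 3 with kidney MV+SA 2. Also after seeing the data, where a named gene's group mean lay below the arrays' 40th percentile, its change was recomputed with each lower value raised to that percentile, with no test. No detection measure was used, so the percentile is only the filter's limit and not a measured background. An array was put in the other class where the 3′ minus 5′ signal of its pyruvate carboxylase control transcript lay 0.8 or more from the organ's median. The labels give no scan date or batch.

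The fit was tested on simulated data made from the organ means and spread of the 15453 genes. The noise was normal and independent between genes, with 1 spread per gene for all organs, and the same genes changed in each organ. Outlying arrays, correlated genes and spreads that differ between organs were left out, so the rates hold only under these assumptions. In the lung 56.7% of genes changed by 0.5 on the log2 scale were recovered, 100% of those changed by 1 and 97% of those changed by 2, with 8 false calls. The shares were 52.2%, 95.5% and 98.5% in the liver and 70.1%, 98.5% and 100% in the kidney, with 9 false calls each, and no recovered gene had the wrong sign.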

Results

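RNA from lung, liver and kidney of C57BL/6 mice was measured on Affymetrix mouse expression arrays with 45101 probe sets. Treated mice, named MV+SA in the labels, were anaesthetised, received about 7 log10 colony-forming units of Staphylococcus aureus in the oropharynx, and were mechanically ventilated for 6 h. Control mice stayed in their cages and received saline under the skin, so the groups differed in infection, ventilation and anaesthesia together. There were 4 control and 5 MV+SA lungs, 3 control and 5 MV+SA livers, and 5 control and 5 MV+SA kidneys, 27 arrays in all. The series title names a model of multiple organ dysfunction in sepsis, and the comparisons ask which genes changed in each organ and which changes the organs shared.

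The number of arrays limits the precision of every value. Arrays of 1 group correlated at r = 0.971 to 0.996 across genes. The labels call the arrays independent without naming the animals, so p-values measure the spread between the arrays as labelled. Each gene has 1 spread shared by all 6 groups, so SEs and p-values in 1 organ also rest on arrays of the other organs. Where a gene is dim in those organs, they can understate its spread in the organ tested. The median log2 signal was 5.67 to 5.75 on lung arrays, 4.00 to 4.05 on liver arrays and 4.61 to 4.66 on kidney arrays, so levels were compared only within an organ. On 4 arrays (lung MV+SA 4, liver control 2, liver MV+SA 5 and kidney MV+SA 5) the 3′-to-5′ signal difference of the pyruvate carboxylase control transcript was 3.27, 2.15, 2.28 and 1.93, against 1.98 to 2.44, 3.88 to 4.20 and 3.63 to 4.30 on the other lung, liver and kidney arrays. Other 3′-to-5′ differences went wholly or partly with treatment. The transferrin receptor transcript gave 1.67 to 1.81 on kidney controls and 1.31 to 1.63 on MV+SA kidneys. Pyruvate carboxylase gave 3.63 to 3.68 on kidney controls 1 to 3 and 4.08 to 4.30 on the rest but MV+SA 5. Actin gave 0.56 to 0.82 on lung controls and 0.39 to 0.55 on MV+SA lungs other than MV+SA 4. The 3′-to-5′ class does not cover these, and they cannot be told apart from treatment.

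**Figure D1:**
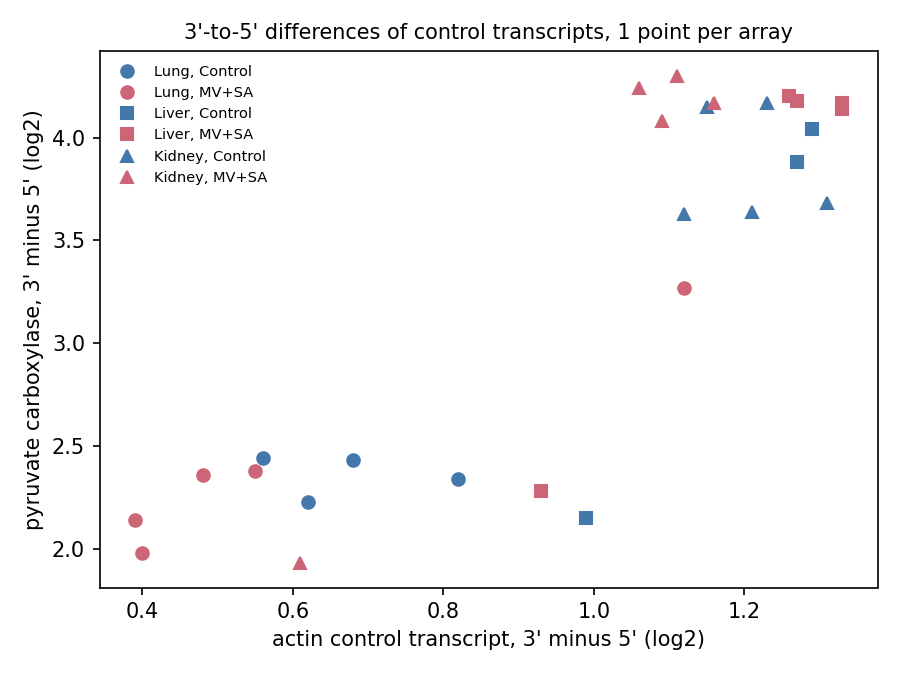
Each point is 1 array; the horizontal axis is the 3′ minus 5′ log2 signal of the actin control transcript and the vertical axis that of pyruvate carboxylase, by organ and treatment. Lung MV+SA 4 lies above the other lung arrays at 3.27, and liver control 2, liver MV+SA 5 and kidney MV+SA 5 lie below the arrays of their organs at 2.15, 2.28 and 1.93.

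In the MV+SA lung, cytokine, chemokine and interferon-inducible genes rose and endothelial markers fell. Cxcl9, an interferon-γ-inducible chemokine for T cells, rose from a mean log2 signal of 4.21 ± 0.30 (SD, n = 4) to 12.38 ± 0.99 (SD, n = 5). Saa3, an acute phase protein, rose by 7.53 (SE 0.34), Cxcl10 by 7.44 (SE 0.31), the macrophage chemokine Ccl3 by 7.36 (SE 0.36), and Acod1, the enzyme that makes itaconate in activated macrophages, by 6.51 (SE 0.16). The tissue inhibitor of metalloproteinases Timp1 rose by 5.11 (SE 0.32) and the anion exchanger Slc26a4 by 3.64 (SE 0.14). Among lower genes, the xenobiotic-metabolising Cyp1a1 fell by 3.26 (SE 0.23), the natriuretic peptide clearance receptor Npr3 by 3.25 (SE 0.20), the apelin receptor Aplnr by 2.87 (SE 0.19) and the endothelial gene Tmem100 by 2.32 (SE 0.12). The control means of Cxcl9 and Ccl3 lay below the 40th percentile of the lung arrays (4.92 to 5.01), so the sizes of their changes rest on dim signals; counted from each array's percentile they were 7.40 and 6.73. Of 15453 genes tested, 4627 (29.9%) changed at an adjusted p under 0.05, 2240 higher and 2387 lower, and 950 of them changed by at least 1 on the log2 scale, 614 higher and 336 lower. With the 3′-to-5′ class as a term 4378 genes passed, and without lung MV+SA 4, the only lung array of the other class, 4228. Because the term marks only that array in the lung, it also leaves the array out and cannot adjust for the class.

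**Figure D2:**
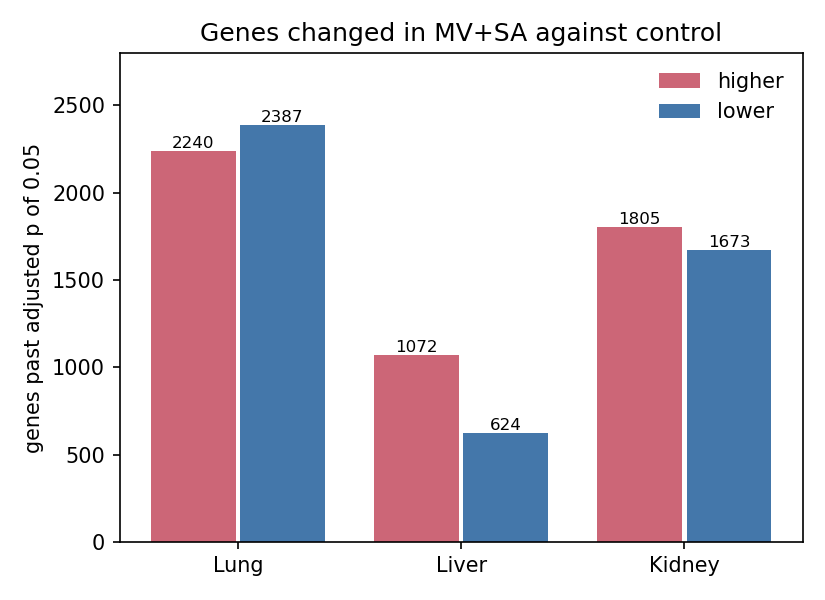
Bars show the number of genes past an adjusted p of 0.05 in MV+SA against control, higher and lower, for each organ. Lung had 2240 higher and 2387 lower genes, liver 1072 and 624, and kidney 1805 and 1673.

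All members tested of 3 inflammatory lists rose in the lung. The 19 acute cytokine and chemokine genes rose (19 adjusted over the list alone; camera adjusted p = 4.93e-24, adjusted p = 0.025 with an estimated correlation), among them the neutrophil chemoattractants Cxcl2 (7.12) and Cxcl3 (5.93) and the chemokine Ccl4 (4.84). The 23 interferon-inducible genes rose (23 adjusted over the list alone; adjusted p = 1.50e-27, adjusted p = 0.036 with an estimated correlation), including the guanylate-binding protein Gbp2 (3.81) and the chemokine Cxcl11 (3.54). The 17 NF-kB feedback and target genes rose (17 adjusted over the list alone; adjusted p = 7.79e-16), including Tnfaip2 (2.86) and the bacterial lipoprotein receptor Tlr2 (2.40), with an adjusted p = 0.057 with an estimated correlation. Among these the Cd14 call was lost without any lung array but MV+SA 1 and MV+SA 2 (limma adjusted p = 0.052 to 0.071). Of 25 acute phase genes 19 rose and Hamp, which encodes hepcidin, fell (19 and 1 adjusted over the list alone; adjusted p = 5.41e-13, adjusted p = 0.057 with an estimated correlation). Its risers included Orm1 (6.17), Saa1 (4.57) and the heme carrier Hpx (3.85). The control means of Cxcl2, Cxcl3, Orm1, Saa1 and Hpx in the lung also lay below the 40th percentile, and their changes counted from it were 6.46, 4.32, 5.76, 3.33 and 3.71. Neutrophil markers moved with these lists: 12 of 18 rose and Camp fell (14 and 1 adjusted over the list alone; adjusted p = 2.86e-09, adjusted p = 0.12 with an estimated correlation), among them the pattern receptors Clec4e (5.66) and Clec4d (3.99) and the growth factor receptor Csf3r (2.84). The change of Camp was -1.05, -0.43 without lung control 4, and its call was lost on lung arrays alone (adjusted p = 0.10). Of 16 monocyte and macrophage markers 6 rose, including the scavenger receptor Marco (2.61) and the integrin Itgam (2.51), and Mrc1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0214, adjusted p = 0.21 with an estimated correlation). That list missed the threshold in a fit on lung arrays alone (adjusted p = 0.068). Of 7 genes of antigen presentation by MHC class II, Ciita (1.78), H2-DMa (1.11) and Ctss (0.87) rose (3 adjusted over the list alone; adjusted p = 0.0160, adjusted p = 0.46 with an estimated correlation).

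Of 21 hypoxia and glycolysis genes 12 rose in the lung, including the glycolytic regulator Pfkfb3 (1.75) and the glucose transporter Slc2a1 (1.66), and Egln1 fell (12 and 1 adjusted over the list alone; adjusted p = 3.24e-06, adjusted p = 0.10 with an estimated correlation). Of 22 unfolded protein response genes 12 rose, including Sdf2l1 (1.86) and Edem1 (1.30), and none fell (12 adjusted over the list alone; adjusted p = 3.63e-05, adjusted p = 0.19 with an estimated correlation). Of 17 oxidative stress and metallothionein genes 10 rose, among them the cystine transporter Slc7a11 (2.92) and the heme-degrading Hmox1 (3.47), while catalase (Cat) and Sod1 fell (10 and 3 adjusted over the list alone; adjusted p = 0.000355, adjusted p = 0.12 with an estimated correlation). The mean of Slc7a11 was below the 40th percentile in control lungs, and its change counted from there was 2.49. The list of 15 heat shock genes did not pass, with 3 lower and 12 not passed (3 lower adjusted over the list alone; median -0.522, adjusted p = 0.137, adjusted p = 0.70 with an estimated correlation). On lung control 2 the heat shock gene Hspa1b was 8.05, against 12.13 to 12.79 on the other lung controls. Of 22 ribosome biogenesis genes 14 rose, including Noc4l (1.22) and nucleolin, Ncl (1.01) (17 adjusted over the list alone; adjusted p = 3.24e-06, adjusted p = 0.19 with an estimated correlation). Of 21 cell cycle genes 12 rose, including the replication helicase subunit Mcm3 (0.98) and the proliferation marker Mki67 (0.80), and Bub1 fell (12 and 1 adjusted over the list alone; adjusted p = 2.81e-05, adjusted p = 0.068 with an estimated correlation). Of 17 genes listed for kidney injury 6 rose, led by Timp1 and the siderophore-binding Lcn2 (3.55), and Il18 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0170, adjusted p = 0.44 with an estimated correlation). Single arrays decided 3 of these falls. Egln1 was not called without lung control 1, control 2, MV+SA 2 or MV+SA 5 (adjusted p up to 0.11). Bub1 was lost without control 1, control 4, MV+SA 2 or MV+SA 4 (adjusted p up to 0.19; -0.23 without control 4). Il18 was lost without any array but control 1 and MV+SA 1 (adjusted p up to 0.15).

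Endothelial and heart muscle markers fell in the lung. Of 16 endothelial markers 11 fell and none rose (11 adjusted over the list alone; adjusted p = 2.26e-07, adjusted p = 0.025 with an estimated correlation), including the receptor kinases Tek (-1.13) and Kdr (-1.06) and the secreted factor Egfl7 (-1.04). By contrast, of 20 genes of endothelial activation and coagulation 11 rose, including P-selectin, Selp (2.68), and tissue factor, F3 (1.88), and Thbd (-1.26), Vwf (-0.83) and Tfpi (-0.44) fell (12 and 3 adjusted over the list alone; adjusted p = 0.00135, adjusted p = 0.24 with an estimated correlation). Markers of other cell types moved with the endothelial fall: 7 of 8 heart muscle genes fell, including Actc1 (-1.50) and Myh6 (-1.18) (7 adjusted over the list alone; adjusted p = 3.34e-07, adjusted p = 0.067 with an estimated correlation). The list of 16 fibroblast and smooth muscle genes did not pass, with 4 lower and 12 not passed (4 adjusted over the list alone; adjusted p = 0.163, adjusted p = 0.50 with an estimated correlation). Of 8 platelet markers 4 fell, led by Ppbp (-0.76) (4 adjusted over the list alone, adjusted p = 0.0288, adjusted p = 0.19 with an estimated correlation). The platelet call was lost on lung arrays alone (adjusted p = 0.074), without lung control 4 (0.051) and without lung MV+SA 3 (0.053). It was also lost with the replicate number as a block across organs (0.056). The Tfpi call was lost without lung control 3, control 4, MV+SA 1, MV+SA 4 or MV+SA 5 (adjusted p up to 0.13). The erythroid genes Bpgm (-1.43), Alas2 (-1.24) and Slc4a1 (-1.21) fell among 4 measured, too few for a list test. Of 19 fatty acid oxidation genes 8 fell, including the thiolase Acaa1b (-2.62) and Hadh (-1.06), and Acadl rose (8 and 1 adjusted over the list alone; adjusted p = 0.00210, adjusted p = 0.30 with an estimated correlation). The Acadl call was lost with the mean of all probe sets (adjusted p = 0.22). The mean of Acaa1b was below the 40th percentile in MV+SA lungs, and its change counted from there was -2.21. Of 6 adipocyte genes 3 were lower and 1 higher in the lung (3 and 1 adjusted over the list alone; median -0.824), and their list did not pass with camera (adjusted p = 0.163, adjusted p = 0.54 with an estimated correlation) but did with fry (adjusted p = 0.031, lower).

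**Figure D3:**
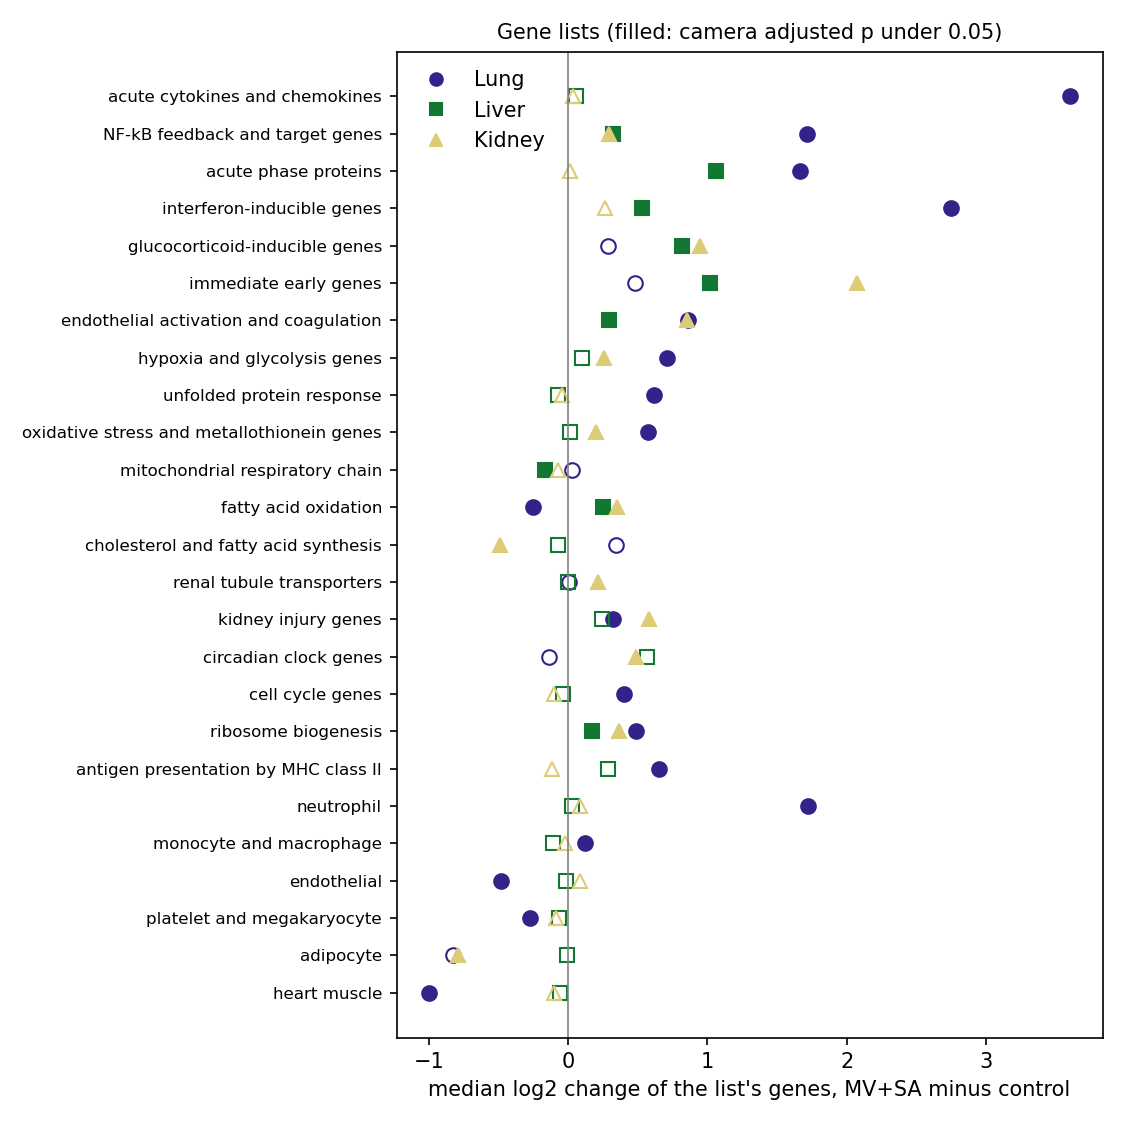
Each point is the median log2 change, MV+SA minus control, of the tested genes of 1 list in 1 organ, for lists past a camera adjusted p of 0.05 in any organ; filled points passed in that organ. The largest median was 3.61 for acute cytokines and chemokines in the lung, and the kidney's largest was 2.07 for immediate early genes.

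In the MV+SA liver, acute phase genes rose as a list (adjusted p = 0.067 with an estimated correlation), the genes Mt1, Mt2 and Cyp2b10 rose and Cyp7a1 fell. The metal-binding Mt2 rose from 6.64 ± 0.84 (SD, n = 3) to 13.28 ± 0.42 (SD, n = 5), 99.7-fold, and Mt1 by 4.74 (SE 0.35). Cyp2b10, a cytochrome induced through the receptor CAR, rose 57.4-fold, from 5.07 ± 0.10 to 10.91 ± 0.80. The growth factor binding protein Igfbp1 rose by 4.38 (SE 0.56), the fasting hormone Fgf21 by 3.46 (SE 0.44) and the lysolipid transporter Mfsd2a by 3.43 (SE 0.36). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 4.32 (SE 0.16), from 10.35 ± 0.46 to 6.03 ± 0.31, and the fatty acid elongase Elovl3 fell by 2.27 (SE 0.27). Both genes had lung and kidney means below the 40th percentile there (3.76 to 3.93 for Cyp7a1). Their SEs, which also rest on those arrays, can understate the spread in the liver. Hsd3b5, a male-biased steroid dehydrogenase, fell by 3.77 (SE 0.64), with liver MV+SA 3 at 3.65 and the other MV+SA livers at 7.96 or higher, and its call was lost on liver arrays alone (adjusted p = 0.072). In all, 1696 genes (11%) changed, 1072 higher and 624 lower, and 345 changed by at least 1 on the log2 scale, 249 higher and 96 lower. The count was 1002 without liver control 3, 814 in a fit on liver arrays alone and 2715 with array weights. It was 1747 with the 3′-to-5′ class as a term and 1410 within the larger class; the other class held 1 control and 1 MV+SA liver. On liver MV+SA 3, 558 genes lay more than 1 from the mean of the other MV+SA livers, and 1414 genes changed without it.

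Of 25 acute phase genes 16 rose in the liver and none fell (18 adjusted over the list alone; adjusted p = 2.63e-18, adjusted p = 0.067 with an estimated correlation). Examples were Lcn2 (4.58), the metalloreductase Steap4 (3.04) and Orm2 (2.85). The list of 17 oxidative stress and metallothionein genes did not pass, with 4 higher, 1 lower and 12 not passed (5 and 2 adjusted over the list alone; median 0.017, mean 0.789, adjusted p = 0.199, adjusted p = 0.81 with an estimated correlation). Of 20 glucocorticoid-inducible genes 10 rose, including Angptl4 (2.41), an inhibitor of lipoprotein lipase, and Sesn1 fell (11 and 2 adjusted over the list alone; adjusted p = 4.56e-07, adjusted p = 0.12 with an estimated correlation). The Sesn1 call was lost without liver control 1, control 3 or MV+SA 3 (adjusted p up to 0.13). Of 23 interferon-inducible genes 7 rose, including Ifit1 (1.85) and Rsad2 (1.75) (8 adjusted over the list alone; adjusted p = 1.99e-06, adjusted p = 0.70 with an estimated correlation). Of 21 immediate early genes 7 rose, including the transcription factors Egr1 (3.78), Junb (3.06) and Jun (2.96) (11 adjusted over the list alone; adjusted p = 0.000149, adjusted p = 0.70 with an estimated correlation). The endothelial activation and coagulation genes Thbd (2.59), Vcam1 (2.06) and Icam1 (1.47) rose among 20 (4 adjusted over the list alone; adjusted p = 0.00959, adjusted p = 0.70 with an estimated correlation). Of 19 fatty acid oxidation genes 5 rose, led by the peroxisomal enzyme Ehhadh (0.85) (7 adjusted over the list alone; adjusted p = 0.00501, adjusted p = 0.70 with an estimated correlation). Of 22 ribosome biogenesis genes 5 rose, including Rrs1 (1.06) and Gnl3 (0.99) (7 adjusted over the list alone; adjusted p = 0.00959, adjusted p = 0.81 with an estimated correlation); the list missed the threshold without liver control 1 (adjusted p = 0.10).

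Other list calls in the liver held genes that depended on single arrays. Of 25 respiratory chain genes Sdhd (-0.44), Cycs (-0.43), Cox7a2 (-0.37) and Atp5o (-0.35) fell (4 adjusted over the list alone; adjusted p = 0.0140, adjusted p = 0.81 with an estimated correlation). None of the 4 was called without liver control 2 or control 3. Sdhd was also lost without MV+SA 3, Cox7a2 without MV+SA 1 or 4, Cycs without MV+SA 1, 2 or 4 and Atp5o without control 1, MV+SA 2 or MV+SA 4 (adjusted p up to 0.18). Of 17 NF-kB genes Bcl3 (1.39) and Tlr2 (0.84) rose (2 adjusted over the list alone; adjusted p = 0.0189, adjusted p = 0.81 with an estimated correlation). That list was lost without liver control 3, MV+SA 2 or MV+SA 3 (adjusted p = 0.068, 0.077 and 0.055), Tlr2 without any control and Bcl3 without any control, MV+SA 1, MV+SA 2 or MV+SA 3 (adjusted p up to 0.14 for each gene). The Tlr2 change was 0.55 without MV+SA 2. Of 24 genes of hepatic drug and bile acid metabolism 5 rose and 5 fell (5 and 6 adjusted over the list alone), with no shift of the list (adjusted p = 0.552). The bile acid enzymes Cyp7b1 (-1.45) and Cyp8b1 (-1.39) fell with Cyp7a1. The median change of 14 hepatocyte secreted proteins was 0.001 (adjusted p = 0.929). Among the liver lists called by camera, fry called only the acute phase and glucocorticoid-inducible lists (adjusted p = 3.9e-05 each). For the others the fry adjusted p was 0.063 to 0.27.

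In the MV+SA kidney, immediate early and fatty acid oxidation genes rose, and genes of cholesterol and fatty acid synthesis fell. None of these 3 lists passed with an estimated correlation (adjusted p = 0.15, adjusted p = 0.15 and adjusted p = 0.28 with an estimated correlation). Pdk4, a kinase that limits glucose oxidation, rose by 3.60 (SE 0.81), from 7.15 ± 0.49 (SD, n = 5) to 10.75 ± 1.83 (SD, n = 5). The glutathione-degrading Chac1 rose by 3.57 (SE 0.31), the cytokine signalling inhibitor Socs3 by 3.37 (SE 0.61), the transcription factors Jun by 3.14 (SE 0.39) and Atf3 by 3.12 (SE 0.55), and the phosphate transporter Slc20a1 by 2.68 (SE 0.27). The interferon-inducible Ifi27l2a fell by 2.02 (SE 0.34), the cholecystokinin receptor Cckar by 1.88 (SE 0.19), the cadherin Cdh11 by 1.65 (SE 0.16) and the prostaglandin-degrading Hpgd by 1.64 (SE 0.25). In all, 3478 genes (22.5%) changed, 1805 higher and 1673 lower, and 275 changed by at least 1 on the log2 scale, 195 higher and 80 lower. The count was 2035 in a fit on kidney arrays alone. It was 3826 with the 3′-to-5′ class as a term and 3677 without kidney MV+SA 5, the only kidney array of the other class. As in the lung, the term here only leaves that array out. On kidney MV+SA 2, 416 genes lay more than 1 from the mean of the other MV+SA kidneys, and 2333 genes changed without it.

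Of 21 immediate early genes 18 rose in the kidney (18 and 2 adjusted over the list alone; adjusted p = 2.25e-11, adjusted p = 0.15 with an estimated correlation), including Fos (3.15) and Egr1 (3.08). Of 19 fatty acid oxidation genes 11 rose, among them the lipid hydroxylase Cyp4a14 (2.62) and the mitochondrial carnitine transferase Cpt1a (0.69) (14 adjusted over the list alone; adjusted p = 1.37e-07, adjusted p = 0.15 with an estimated correlation). Of 20 glucocorticoid-inducible genes 12 rose, including the phosphatase Dusp1 (1.85) (14 and 1 adjusted over the list alone; adjusted p = 1.37e-07, adjusted p = 0.15 with an estimated correlation). Of 20 genes of endothelial activation and coagulation 13 rose, including the protease Adamts1 (2.57), F3 (2.33) and Thbs1 (1.80) (15 and 1 adjusted over the list alone; adjusted p = 2.46e-06, adjusted p = 0.15 with an estimated correlation). Of 22 ribosome biogenesis genes 10 rose, including Nop58 (1.56) and Gnl3 (1.21) (13 adjusted over the list alone; adjusted p = 5.51e-06, adjusted p = 0.32 with an estimated correlation). Of 18 cholesterol and fatty acid synthesis genes 9 fell and none rose, among them the isoprenoid enzymes Idi1 (-1.69) and Mvd (-1.47) and fatty acid synthase, Fasn (-1.11) (10 adjusted over the list alone; adjusted p = 5.11e-05, adjusted p = 0.28 with an estimated correlation).

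Of 17 kidney injury genes 5 rose in the kidney, including Lcn2 (2.66) and the keratin Krt18 (0.75), and Mdk fell (8 and 1 adjusted over the list alone; adjusted p = 0.00268, adjusted p = 0.38 with an estimated correlation). Krt18 was 9.02 on kidney MV+SA 2, against 7.99 to 8.26 on the other MV+SA kidneys. Without that array its change was 0.58 and that of Lcn2 1.83, and the list and both genes stayed called. Of 17 clock genes Per1 (1.47), Bhlhe40 (1.46) and Nr1d2 (0.82) rose (3 adjusted over the list alone; adjusted p = 0.00577, adjusted p = 0.15 with an estimated correlation). Among kidney controls the clock output gene Dbp was 9.99 on control 4, against 7.05 to 9.0 on the others, and Nr1d2 was 9.36 on control 3, against 9.88 to 9.96. The clock list stayed called without control 4 (adjusted p = 0.0065) or control 3 (0.014), and the Nr1d2 change was 0.71 without control 3. Of 17 oxidative stress genes 4 rose, including Mt2 (2.83) and Hmox1 (2.06) (5 adjusted over the list alone; adjusted p = 0.00577, adjusted p = 0.32 with an estimated correlation). Of 26 tubule transporters 7 rose, led by the collecting duct water channel Aqp2 (1.13), and Slc7a13 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00577, adjusted p = 0.38 with an estimated correlation), a call lost without kidney control 1 (adjusted p = 0.079). Of 17 NF-kB genes 3 rose, led by Nfkbiz (1.76) (3 adjusted over the list alone; adjusted p = 0.00621, adjusted p = 0.58 with an estimated correlation), and of 21 hypoxia genes Ndrg1 (0.70) and Slc2a1 (0.51) rose (1 adjusted over the list alone; adjusted p = 0.0200, adjusted p = 0.49 with an estimated correlation). Both list calls were lost without kidney MV+SA 2 (adjusted p = 0.069 and 0.15), and that of hypoxia also without control 1 (0.051). The NF-kB list was also lost with the mean of all probe sets (0.057), and the hypoxia list with the 60th percentile filter (0.053) and array weights (0.064). With fry the NF-kB list did not pass either (adjusted p = 0.11). The Slc2a1 call was lost without control 1, control 4, MV+SA 2 or MV+SA 3 (adjusted p up to 0.14). That of Mdk (-0.49) was lost without control 4, MV+SA 2 or MV+SA 3 (adjusted p up to 0.13; -0.32 without MV+SA 2). The unfolded protein response list did not pass (adjusted p = 0.142) and its median (-0.047) and mean (0.47) differed in sign. Ddit3 (2.29) and Asns (2.30) rose and the chaperones Pdia6 (-0.47), Dnajb11 (-0.42) and Calr (-0.41) fell (6 and 4 adjusted over the list alone), with Dnajb11 lost without kidney control 5 or MV+SA 2 (adjusted p up to 0.068) and Pdia6 with the mean of all probe sets (0.051). Markers of fat moved with the fall in lipid synthesis genes: of 6 adipocyte genes Adipoq (-1.59), Car3 (-1.08) and Retn (-0.88) fell (4 adjusted over the list alone; adjusted p = 0.0497, adjusted p = 0.49 with an estimated correlation). That list call was lost in 17 of the 27 fits that left out 1 array (adjusted p up to 0.23, without kidney control 4). Other settings ended it too, among them array weights (0.53), the 3′-to-5′ class as a term (0.11), leaving out the 4 arrays of the other class (0.12) and kidney arrays alone (0.063). Car3 was lost without control 3, control 4, MV+SA 2 or MV+SA 3 (adjusted p up to 0.10). With array weights all 3 genes were lost (adjusted p = 0.16 for Adipoq, 0.20 for Car3 and 0.39 for Retn). The median change of 18 neutrophil markers was 0.089 in the kidney (adjusted p = 0.329) and 0.028 in the liver (adjusted p = 0.552).

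Across all organs 168 genes changed the same way, 128 higher and 40 lower, where independent lists of these sizes would share 18.2 and 10.4. Without liver control 3 the number was 110, and with array weights 329. Shared higher genes included Mt2, Lcn2, Socs3, Junb, the clock repressor Bhlhe40 and the acute phase transcription factor Cebpb. Mt2 was higher by 4.25 in lung, 6.64 in liver and 2.83 in kidney, and Bhlhe40 by 1.86, 1.85 and 1.46. Shared lower genes included the stress kinase Map2k6, lower by 0.69, 0.96 and 0.73, and the hydrolase Rbbp9, at -0.77, -0.70 and -0.97. Of the 15 higher and 10 lower genes named for this comparison, 7 and 6 lost a call in some organ when 1 array was left out, and those given here did not. Liver and kidney shared 458 higher genes (125.2 for independent lists) and 189 lower, and 93.5% of 692 genes called in both had the same sign. The corresponding shares were 74.2% of 573 for lung and liver and 69.4% of 1064 for lung and kidney. The log2 changes correlated across genes, which are not independent replicates, at r = 0.458 (rho = 0.436) for liver and kidney, 0.219 (0.183) for lung and liver and 0.191 (0.171) for lung and kidney. For lung and kidney 12 of 100 splits of the arrays, the real one included, gave a correlation as large. The highest other split gave 0.23 for lung and liver and 0.457 for liver and kidney. No control array was shared between organs, though the labels do not say whether 1 animal gave several organs. If so, the errors of 2 organs would be linked, which could raise these correlations and the shared counts. Array deviations from the group mean correlated at 0.535 for lung control 4 and kidney control 1, and at 0.391 for liver control 1 and kidney control 4.

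**Figure D4:**
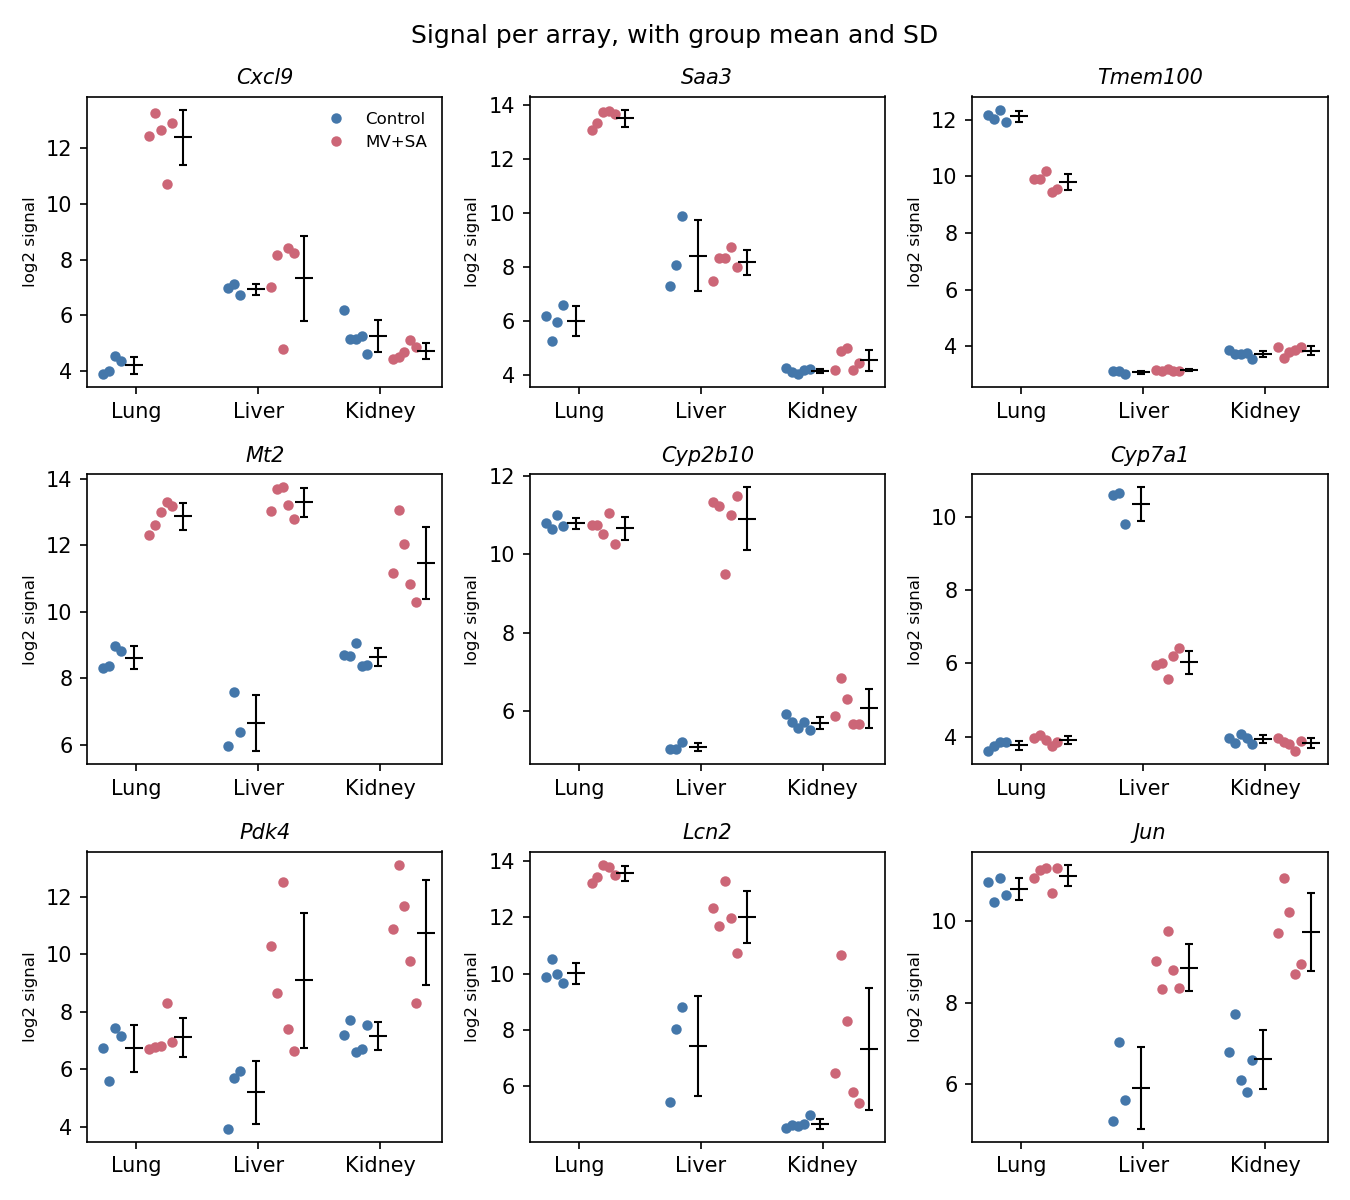
Points are the log2 signals of single arrays for 9 genes in control and MV+SA lung, liver and kidney, with each group's mean and SD beside them; levels compare only within an organ. Cxcl9 and Saa3 separated the groups in the lung, Cyp2b10 and Cyp7a1 in the liver, and Mt2 in all 3 organs.

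Tests of the difference in response between organs called 3303 genes for lung against liver, 4046 for lung against kidney and 722 for liver against kidney. The last count was 400 in fits of each organ's own arrays and 1225 with array weights. The response of Cxcl9 was larger in the lung by 7.79 (SE 0.76) than in the liver and by 8.73 (SE 0.71) than in the kidney, and that of Acod1 by 6.36 and 6.52. Counted from the 40th percentile of each array, because its mean in control lungs lay below it, the Cxcl9 differences were 7.01 and 7.95. Both kidney means of Acod1 lay below it. The Cyp2b10 response was larger in the liver than in the lung and the kidney, by 5.97 and 5.46. Some genes changed in opposite directions: Mfsd2a rose by 3.43 in the liver and fell by 1.90 in the kidney (difference 5.33, adjusted p = 5.2e-08). The endothelin receptor Ednrb fell by 1.94 in the lung and rose by 1.36 in the kidney, and thrombomodulin, Thbd, fell by 1.26 in the lung and rose by 2.59 in the liver. Lists that responded more in the lung than in both other organs included acute cytokines (adjusted p = 2.1e-20 against liver and 5.1e-19 against kidney; adjusted p = 0.054 and 0.039 with an estimated correlation). The response of fatty acid oxidation genes was lower in the lung than in the kidney (adjusted p = 4.5e-09; adjusted p = 0.060 with an estimated correlation), and that of cholesterol and fatty acid synthesis genes was lower in the kidney than in the liver (adjusted p = 0.00015; adjusted p = 0.85 with an estimated correlation). The response of endothelial markers was lower in the lung than in the kidney (adjusted p = 3.3e-08, adjusted p = 0.029 with an estimated correlation). Against the liver it was also lower (adjusted p = 1e-05), but did not pass with an estimated correlation (adjusted p = 0.079).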

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

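The tests of the 3 array patterns weighed here and the differences counted from the 40th percentile were chosen only after the results were seen, and the counts over other splits of the arrays were planned. Responses differed between organs by a test of the difference itself for 3303 genes (lung against liver), 4046 (lung against kidney) and 722 (liver against kidney). In limma fits of 100 splits of the arrays, the real one included, the highest other split gave 2226, 2254 and 924. Of the 100, 1, 1 and 2 were as large as the real one. The splits mixed the treatment labels in every organ, so they ask whether the treatment had any effect. They cannot decide whether 2 organs responded differently. The lung response minus the liver response was 7.79 for Cxcl9, 7.77 for Saa3, 7.35 for Ccl3, 7.00 for Cxcl2 and 6.36 for Acod1, and -5.97 for Cyp2b10, -4.26 for Igfbp1, -3.86 for Thbd, -3.66 for Klf10 and -3.47 for Fgf21. The lung response minus the kidney response was 8.73 for Cxcl9, 7.19 for Ccl3, 7.14 for Saa3, 6.89 for Orm1 and 6.74 for Cxcl10, and -3.30 for Ednrb, -3.22 for Pdk4, -3.19 for Fabp1, -3.06 for Acaa1b and -2.96 for Cyp1a1. The Pdk4 call was lost in 14 of the 19 fits that left out 1 lung or kidney array (adjusted p = 0.051 to 0.095), all but those without lung control 2, lung MV+SA 4, kidney control 2, kidney MV+SA 4 or kidney MV+SA 5. It was also lost with no filter (0.054), trend and robust settings (0.060) and the replicate number as a block across organs (0.052), over a range of 0.0034 to 0.095. The liver response minus the kidney response was 5.46 for Cyp2b10, 5.33 for Mfsd2a, 3.81 for Mt2, 3.12 for Steap4 and 2.99 for 2010003K11Rik, and -4.21 for Cyp7a1, -3.65 for Hsd3b5, -3.56 for Serpina4-ps1, -3.29 for Tsc22d1 and -3.12 for Ccn1. With the mean of all probe sets the Ccn1 difference was -1.83 and not called (adjusted p = 0.11; 0.00054 to 0.11 over its alternatives), and that of Tsc22d1 was -1.94 and still called. The Hsd3b5 call was lost in fits of each organ's own arrays (adjusted p = 0.063; 1.4e-08 to 0.063 over its alternatives). Some of these sizes rest on dim signals and are not ranked here. The mean of control lungs lay below the 40th percentile of their arrays for Cxcl9, Ccl3, Cxcl2 and Orm1, and that of MV+SA lungs for Fabp1 and Acaa1b. Counted from that percentile, the lung response minus the liver response was 7.01 for Cxcl9, 6.76 for Ccl3 and 6.49 for Cxcl2. Minus the kidney response it was 7.95 for Cxcl9, 6.75 for Ccl3, 6.12 for Orm1, -2.92 for Fabp1 and -2.64 for Acaa1b. Both group means lay below it in the lung for Igfbp1 and Fgf21, in the liver for Ccl3 and Cxcl2, and in the kidney for Ccl3, Cyp1a1, Cyp7a1, Hsd3b5, Serpina4-ps1 and 2010003K11Rik.

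Single arrays lay far from the rest of their group for 28 values in 389 groups of 4 or 5 arrays, by Dixon's gap ratio at the 95% level. Chance alone gives about 1 in 20 groups, or 19.4 here. In the kidney controls these were Orm1 (5.49, others 4.11 to 4.44) and Cpt1a (9.86, others 10.48 to 10.69) on control 1, Chac1 (4.99, others 5.43 to 5.60) and Nr1d2 (9.36, others 9.88 to 9.96) on control 3, and Aqp2 (9.53, others 9.16 to 9.26) on control 4. Among MV+SA kidneys they were Mvd on MV+SA 3 (7.05, others 6.53 to 6.61) and Aqp2 on MV+SA 4 (10.27, others 10.43 to 10.48). Kidney MV+SA 2 was high for 2010003K11Rik (5.33, others 3.62 to 4.05), Cxcl10 (7.77, others 5.90 to 6.33), Krt18 (9.02, others 7.99 to 8.26), Mfsd2a (6.73, others 4.81 to 5.31) and Slc2a1 (9.69, others 9.02 to 9.16). In the liver they were Angptl4 on MV+SA 2 (9.30, others 10.01 to 10.03) and, on MV+SA 5, Ccl3 (3.58, others 3.11 to 3.24) and Sult5a1 (5.74, others 6.26 to 6.47). Liver MV+SA 3 was low for Cyp2b10 (9.51, others 11.01 to 11.48) and Hsd3b5 (3.65, others 7.96 to 9.0). Lung MV+SA 1 stood apart for Abca3 (10.61, others 10.31 to 10.38), Ednrb (8.86, others 8.07 to 8.29), Kdr (10.24, others 9.64 to 9.71), Myh6 (10.26, others 9.52 to 9.73) and Edem1 (9.35, others 9.68 to 9.82). Lung MV+SA 4 did so for Ctss (12.97, others 13.22 to 13.32), Gbp2 (12.75, others 13.49 to 13.75) and Pdk4 (8.32, others 6.71 to 6.95). In lung controls they were Ncl (10.05, others 10.43 to 10.50) and Sftpd (13.73, others 13.61 to 13.63) on control 2 and Socs3 (9.47, others 8.75 to 8.85) on control 3.

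Lung MV+SA 4, liver control 2, liver MV+SA 5 and kidney MV+SA 5 differed from the other arrays of their organ in the 3′-to-5′ difference of the pyruvate carboxylase control transcript. The treatment as the whole cause is argued against, since only 2 of the 10 liver and kidney MV+SA arrays were of the other class and liver control 2 was too. Over all organs the class held 3 of 15 MV+SA arrays and 1 of 12 controls. These counts pool opposite shifts, since lung MV+SA 4 lay above its organ and the liver and kidney arrays below theirs. A part played by the treatment stays open. For a different labelling or RNA preparation batch, the actin and Gapdh control transcripts put the same arrays outside the range of their organ in 8 of 8 cases, in the direction of pyruvate carboxylase. The transferrin receptor transcript did so in 1 of 4, kidney MV+SA 5 (1.31, others 1.41 to 1.81), while both livers (1.05 and 1.01) lay inside 0.98 to 1.32 and lung MV+SA 4 (2.17, others 2.26 to 2.53) lay on the opposite side. For that transcript all MV+SA kidneys (1.31 to 1.63) lay below all kidney controls (1.67 to 1.81). No label names a batch, so a batch may be a cause but stays open.

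Kidney MV+SA 2 stood apart from the other MV+SA kidneys, with 318 genes more than 1 above their mean and 98 more than 1 below. The other 3′-to-5′ class is argued against, because its pyruvate carboxylase 3′-to-5′ difference lay 0.19 from the kidney median. RNA degradation stays open. That difference (4.30) and the Gapdh difference (0.21, others -0.24 to 0.17) were the highest of the kidney arrays, while the actin difference (1.11) lay inside the others' 0.61 to 1.31. RNA of added neutrophils alone would not raise tubule epithelium genes, yet the median deviation of 6 such genes was 1.62. It was 1.00 without Havcr1, whose 2.24 was near the SD of the other arrays, 1.80. Krt20 lay 5.16 (SD 0.33) and Sox9 2.45 (SD 0.26) above, and the median of the neutrophil list was 0.26 above. Added neutrophil RNA alone is argued against for these genes. All 6 are also on the kidney injury list and could rise with injury, so injury with more neutrophils stays open. No other cause was tested.

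In each organ 1 control (lung control 2, liver control 1 and kidney control 4) had higher Dbp, a clock output gene, and lower Hspa1b, a heat shock gene, than the other controls. Dbp was 10.42, 10.11 and 9.99, against 8.21 to 8.53, 4.61 to 5.01 and 7.05 to 9.0, and Hspa1b was 8.05, 7.99 and 9.44, against 12.13 to 12.79, 11.53 to 11.55 and 10.30 to 12.14. RNA degradation or the other 3′-to-5′ class is argued against, the largest distance of these arrays from their organ's median being 0.07. Another phase of the daily clock at harvest may be the cause, since 27 of 27 cases of 9 other clock genes lay on the side predicted. The labels give no time of harvest or animal for these arrays, and the lower heat shock genes (15, 12 and 14 of 15) were not explained by a test.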

How the results depend on the processing

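The alternatives with a 3′-to-5′ class term, those leaving out sets of arrays and the changes counted from the 40th percentile were chosen only after the data were seen; the other alternatives and the splits were planned. Across 407 named gene results and 9648 values of them under the alternatives none changed direction, and 303 stayed called under every alternative but the size limit. These results were picked as called and mostly large, which makes reversals unlikely. Over all genes called, 25 lung, 4 liver and 11 kidney calls took the opposite sign with the mean of all probe sets. With quantile normalization over all arrays 4, 0 and 4 did. Among the named results the size limit ended 136 calls, fits of each organ's own arrays 66, the mean of all probe sets and leaving out the 4 arrays of the other 3′-to-5′ class 31 each, and the block within organ 29. Of the 123 results that involve the liver, 34 lost their call without liver control 3 and 25 without liver control 2. With the size limit of 1, by its construction, 950 genes passed in the lung, 345 in the liver, 275 in the kidney and 22 in all 3 organs, and 1106, 1139 and 285 for lung against liver, lung against kidney and liver against kidney. Each organ's own arrays gave 814 in the liver, 2035 in the kidney and 400 for liver against kidney. Array weights gave 2715 in the liver, 329 in all organs, 4981 for lung against liver and 1225 for liver against kidney; the cause was not tested. Camera with an estimated correlation called 3 lung, 0 liver and 0 kidney lists (10, 2 and 5 at an unadjusted p under 0.05), and fry called 23, 2 and 17. Leaving out 1 array of the organs concerned gave 4004 to 4631 genes in the lung, 1002 to 1766 in the liver, 2333 to 3677 in the kidney and 110 to 203 in all organs. The liver and all-organ lows, without liver control 3, were the only counts to move by over 1.5 times. The ranges were 2664 to 3368, 3445 to 4089 and 494 to 798 for the differences between organs, in the order above, 17 to 20, 8 to 9 and 10 to 14 for lists in lung, liver and kidney, and 0.203 to 0.226, 0.163 to 0.212 and 0.428 to 0.471 for the correlations. With the class term 4378, 1747 and 3826 genes passed in lung, liver and kidney, without the 4 arrays of the other class 4358, 1410 and 3783, and without liver MV+SA 3 and kidney MV+SA 2 4984, 1576 and 2566. In lung and kidney the class term marks 1 array, so there the first 2 settings leave out the same array and are not separate checks. The share of higher calls in the kidney, 51.9%, was 42.2% with quantile normalization over all arrays. With the replicate number as a block within organ 3868, 1550 and 3148 genes passed, and as a random block across organs 4634, 1688 and 3487. The numbers were not taken to pair the arrays, since not every same-number pair correlated above 0.1: 5 of 12 did within an organ (-0.11 to 0.214) and 6 of 25 across organs (-0.362 to 0.453). As a hint from the data, 11 of the 12 within an organ were above 0, against 18 of 48 other pairs, and 11 of the 24 arrays with a partner correlated best with their own number, where chance gives 5.4. Across organs, pairs with different numbers reached 0.535 (lung control 4 and kidney control 1), and 47 of 97 such pairs were above 0. Organs of 1 animal may thus carry different numbers, which was not tested. Over other splits of the arrays, the real split called the most genes in each organ. In the lung it called 4627, against at most 3806, with lung MV+SA 1 moved to the controls (1 of 100 splits as large). In the liver it called 1696 against 707 (1 of 56) and in the kidney 3478 against 1404 (1 of 100). For all organs the counts were 168 against 0 (1 of 100), with the labels of every organ mixed at once. The median split of 1 organ called 0 genes, so a shared count of 0 says only that the organs responded. It does not test the sharing between them. For the correlations, splits as large numbered 2 of 100 for lung and liver (0.219, highest other 0.23) and 1 of 100 for liver and kidney (0.458, highest other 0.457). For lung and kidney they numbered 12 of 100 (0.191, highest other 0.274). Few splits were as large for the first 2 pairs, but the highest others lay close to the real values. Chance is therefore not called excluded for any correlation. Chance was also not excluded for the number of lists in the lung (18 against 20, 23 of 100), liver (9 against 11, 15 of 56) or kidney (13 against 16, 13 of 100). Signal over background was not analysed here, and small changes were limited by the number of arrays.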

Other observations

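All tests of the hypothesis given here were chosen only after the liver result was seen, and Cd3g, Sftpd, Foxj1, Acta2, Hspa5 and the receptor targets were named after their values were seen. In the MV+SA lung, lymphocyte markers moved both ways and the list as a whole did not pass (5 higher, 6 lower and 6 not passed of 17; 5 and 6 adjusted over the list alone; camera adjusted p = 0.561, median -0.016). The B cell genes Ms4a1, Cd79a and Cd79b fell by 2.01, 1.14 and 1.10, with all 5 MV+SA lungs below all 4 controls for each gene. Nkg7, a cytotoxic granule gene, rose by 1.23 and the T cell receptor complex gene Cd3g by 0.89, each above all controls on 4 of 5 MV+SA arrays. The exception was lung MV+SA 4, and the Nkg7 call was lost on lung arrays alone (adjusted p = 0.051; 3e-08 to 0.051 over its alternatives). Of 16 lung epithelial genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.227, median -0.147). The club cell enzyme Cyp2f2 fell by 1.30 and the surfactant lipid transporter Abca3 by 0.88. The surfactant protein gene Sftpd rose by 0.44 and Foxj1, a regulator of ciliated cells, by 0.45, and each of these 4 genes separated all 5 MV+SA lungs from all controls.

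In the MV+SA kidney, Col3a1 fell by 1.33, Col1a1 by 0.88 and Col1a2 by 0.79, each lower on all 5 MV+SA arrays than on all 5 controls. The list of 16 fibroblast and smooth muscle genes did not pass (2 higher, 4 lower and 10 not passed; 2 and 6 adjusted over the list alone; adjusted p = 0.229, median -0.147). The smooth muscle actin gene Acta2 rose by 0.55, above all controls on 3 of 5 arrays. The replication helicase genes Mcm6 and Mcm5 fell by 0.86 and 0.76, each below all controls on all 5 MV+SA arrays, while the list of 21 cell cycle genes missed the threshold (0 higher and 3 lower, with the same counts adjusted over the list alone; adjusted p = 0.0938, median -0.098). In the liver, 3 of 22 unfolded protein response genes rose and 4 fell (4 and 4 adjusted over the list alone). The list did not pass (adjusted p = 0.798), with a median of -0.074, a mean of 0.017 and a test pointing down. Chac1 rose by 2.78 in 5 of 5 MV+SA livers. The endoplasmic reticulum chaperone gene Hspa5 fell by 0.76, below all controls on 4 of 5 arrays, and its call was lost without liver control 3 (adjusted p = 0.086) and on liver arrays alone (0.12; 4.2e-05 to 0.12 over its alternatives).

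Cyp2b10 rose by 5.84 in 5 of 5 MV+SA livers, and a hypothesis was that genes induced by the xenobiotic receptors CAR and PXR rose broadly, which anaesthetic drugs might cause. Of 21 other targets listed for the test, 14 were tested. Genes on any list used here, such as that of hepatic drug and bile acid metabolism, were left out of it. That list had 5 higher and 5 lower of 24 genes in the liver. The median liver change of the 14 targets was -0.08, at percentile 29.7 of 10000 random lists matched on mean expression. This argues against a broad rise among these 14, and the targets left out were not covered. Gstt3 (0.58) and Slco1a4 (0.38) rose and Ugt2b35 (-0.52) and Sult5a1 (-0.65) fell. The Slco1a4 call was lost without liver control 1, control 3, MV+SA 4 or MV+SA 5 (adjusted p up to 0.22; 0.00083 to 0.31 over its alternatives), and that of Ugt2b35 without control 1 or control 2 (up to 0.054; 0.0017 to 0.17). What raised Cyp2b10 stays open, and anaesthesia, ventilation and infection were not separated by the design.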
